A study of Homo sapiens with 12 samples.

How the data were processed

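RNA was measured in 12 cultures of isogenic MCF-10A lines, 4 of the HER2-mutant line, 4 of the PIK3CA-mutant line and 4 of both together. Per the labels' protocols, cells grew in medium with a physiologic amount of EGF and were harvested between day 7 and day 14, RNA was purified on columns, and 5 µg was labelled with a whole-transcript kit. The deposited values are log2 probe-set signals that the authors made with the Transcriptome Analysis Console, per the submitters' processing notes. The notes give no version, and name no method of background correction, summarization or normalization. The values had near equal medians, 6.41 to 6.49, without being identical in distribution between arrays, and were used as they stand. The number of arrays, 4 per group, limits the precision. Arrays were assigned to groups by their labels, and 0 were left unassigned.

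Of 24351 probe sets, 17709 were named for exactly 1 gene symbol in the annotation of the series. The 3739 probe sets without a gene name and the 2903 control and other probe sets were left out. The named probe sets covered 17687 genes. For the 20 genes with several probe sets, the brightest was used. In 1 of these 20 the probe sets differed in direction between the single cultures. A probe set was kept if its signal was above the 30th percentile of its array on at least 4 of the 12 arrays, which left 12758 genes. ERBB2 and PIK3CA had no named probe set in use and were not analysed here. No coordinates are given, since the genome build was not named.

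In limma 3.58.1 (R 4.3.3), a linear model with the 3 groups was fitted to all 12 arrays, with empirical Bayes moderation and a trend of the spread with signal. Contrasts between groups were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold, and a second count was taken at an absolute log2 difference of at least 1. The expected blend was formed on the linear scale from 75% of the HER2-mutant and 25% of the PIK3CA-mutant mean. The difference of the co-culture from it was divided by the moderated standard error with delta-method weights, and a second count was taken at 0.5 on the log2 scale. A gene was outside both single cultures when the co-culture lay above both or below both. Its p was the larger of both contrast p-values, and its difference is the smaller of both. The signal share was the median over genes of the position of the co-culture between the single cultures on the linear scale. Genes for the share were chosen on replicates 1 and 2 of the single cultures and measured on replicates 3 and 4, and the reverse. They differed between the lines with an adjusted p under 0.05 and by at least 1 on the log2 scale.

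The 25 gene lists were those of ERK output, FOXO targets, ERBB receptors and ligands, cell cycle, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, amino acid response, chaperones of the endoplasmic reticulum, heat shock, NRF2 targets, interferon response, antigen presentation, inflammatory cytokines, secreted growth factors, mesenchymal, luminal, basal and squamous genes, matrix proteases, p53 targets, YAP targets, NOTCH and WNT targets, fibroblast markers, and blood and endothelial markers. They were tested with camera at a preset correlation of 0.01 between genes, and with cameraPR for the blend, with p adjusted over the 25 lists within a comparison. Camera with the correlation estimated from the residuals was the alternative. In the pairwise comparisons it raised the adjusted p also for lists whose estimate was below the preset, so it changed more than the correlation. Members were counted over all genes and adjusted over the list alone. A list that a comparison's text does not mention did not pass there.

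Groups, comparisons, tests, lists, thresholds and the rule for named genes were chosen before the data were examined. The rule named the genes with the largest differences whose arrays did not overlap between groups, 10 in each direction between the single cultures, against the blend and outside both, and 6 in each direction for the co-culture against each line. It also named EGFR and ERBB3, and up to 4 members of each list past the threshold. Fewer list members than the rule allows are printed, and the choice among them was made after their values were seen.

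The method was tested on simulated data with 50 changed genes per step. Between the single cultures, 42% of changes of 0.5 on the log2 scale, 88% of changes of 1 and 100% of changes of 2 were called. The corresponding figures were 56%, 96% and 100% against the blend and 36%, 86% and 100% outside both. For these, the changed genes were simulated at equal levels in both lines, whereas 59.5% of the measured genes differed between the lines. Of the calls, 2.37%, 6.38% and 0% were false. Data without change gave 0 calls. A simulated share of 75% was recovered as 74.9%. Exact blends of the measured means, at 25%, 50% and 75%, gave 0 genes outside both. That count was all but fixed, since each simulated mean lay between the lines and the noise was the residual spread alone.

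Replicate numbers did not pair the cultures. After removal of group means, arrays of the same number correlated between -0.034 and 0.060, 0 of 12 pairs exceeded 0.1, and the best match had the same number in 5 of 24 comparisons.

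Alternatives were no filter or one at the 50th percentile, quantile normalization, median centring, no trend, a robust trend, array weights, the replicate number as a block, mean probe sets and leaving out each array. Others were fits on the compared groups alone, a tested margin of 0.5 (limma treat), other shares for the blend, a blend on the log2 scale, separate adjustment of both contrasts and estimated correlations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.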

Results

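RNA from 12 cultures of MCF-10A, a non-tumorigenic human breast epithelial cell line, was measured on whole-transcriptome arrays. One line carried the HER2 L755S mutation, in the kinase domain of the receptor HER2. The other carried the PIK3CA E545K mutation, in the catalytic subunit of the lipid kinase PI3K. Each line was grown alone on 4 arrays (single cultures), and the 2 lines were grown together on 4 further arrays (co-culture). Per the labels, the co-cultures were harvested when about 75% of the cells carried the HER2 mutation, by droplet digital PCR. No MCF-10A line without a mutation was analysed here, so a difference between the lines does not say which of them moved. The values were log2 probe-set signals as the submitters deposited them. The median signal of an array was 6.41 to 6.49, and the median of its negative control probe sets was 3.39 to 3.79. For a gene close to that background in one group, the difference given is a lower limit in size. The number of arrays, 4 per group, limits the precision of every value. Probe sets named for ERBB2, the HER2 gene, or for PIK3CA itself were not used here, so the genotype of a culture was not checked against its signal.

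The 3 groups were clearly apart, and the co-culture lay closer to the PIK3CA-mutant line. Across 12758 genes the median correlation between arrays was 0.992 within the HER2-mutant line, 0.9954 within the PIK3CA-mutant line and 0.9946 within the co-culture. It was 0.9223 between the single cultures, 0.9486 between the co-culture and the HER2-mutant line, and 0.9857 between the co-culture and the PIK3CA-mutant line. These correlations are across genes, which are not independent replicates. The first principal component held 79.5% of the variance and the second 7.35%.

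Comparing the single cultures asked how the lines differed. Each mutation was carried by a single line, as far as the labels say, and the harvest day of each array is not given. A difference between the lines therefore cannot be assigned to the mutation alone, or told apart from a difference in harvest. The HER2-mutant culture expressed far less of most listed ERK output genes, of the genes of S phase and mitosis, and of most genes that make cholesterol and fatty acids. It expressed more of many genes that FOXO factors induce and of the machinery that presents antigen on MHC class I, list calls that were lost with the correlation estimated from the arrays (p 0.109 and 0.05). Transcripts far higher in it included GREB1, TSHZ2, the FOXO target FBXO32 and the complement proteases C1S and C1R. The PIK3CA-mutant culture stood out by the matrix protein genes THBS1 and FN1, by NT5E (the ecto-enzyme CD73) and by the ERK phosphatase gene DUSP6. By limma, 3828 genes were higher and 3759 lower in the HER2-mutant line, 59.5% of the 12758 tested, and 1150 and 1563 of them differed by at least 1 on the log2 scale. Against a tested margin of 0.5 on the log2 scale the count was 3524 genes.

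GREB1 had the largest positive difference and THBS1 the largest negative one. In limma, GREB1 was higher in the HER2-mutant line by 9.29 ± 0.20 on the log2 scale (SE, adjusted p 1.26e-20), from 3.69 ± 0.40 to 12.98 ± 0.22 (SD, n = 4 each). FBXO32 was higher by 7.58, TSHZ2 by 7.30, C1S by 7.29, C1R by 6.78, WNT4 by 6.38, SELENOP by 6.11, ALOX5AP by 5.92, CD36 by 5.90 and CHI3L2 by 5.63. In the opposite direction, THBS1 differed by -10.25 ± 0.22 (SE, limma adjusted p 1.44e-20), from 15.62 ± 0.17 in the PIK3CA-mutant line to 5.37 ± 0.49 in the HER2-mutant line (SD, n = 4 each). NT5E differed by -9.34, DUSP6 by -8.65, ABCC3 by -8.28, CASP14 by -8.14, OSBP2 by -7.76, TSPAN1 by -7.65, LIPG by -7.36, CLDN1 by -7.34 and FN1 by -7.30.

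**Figure D1:**
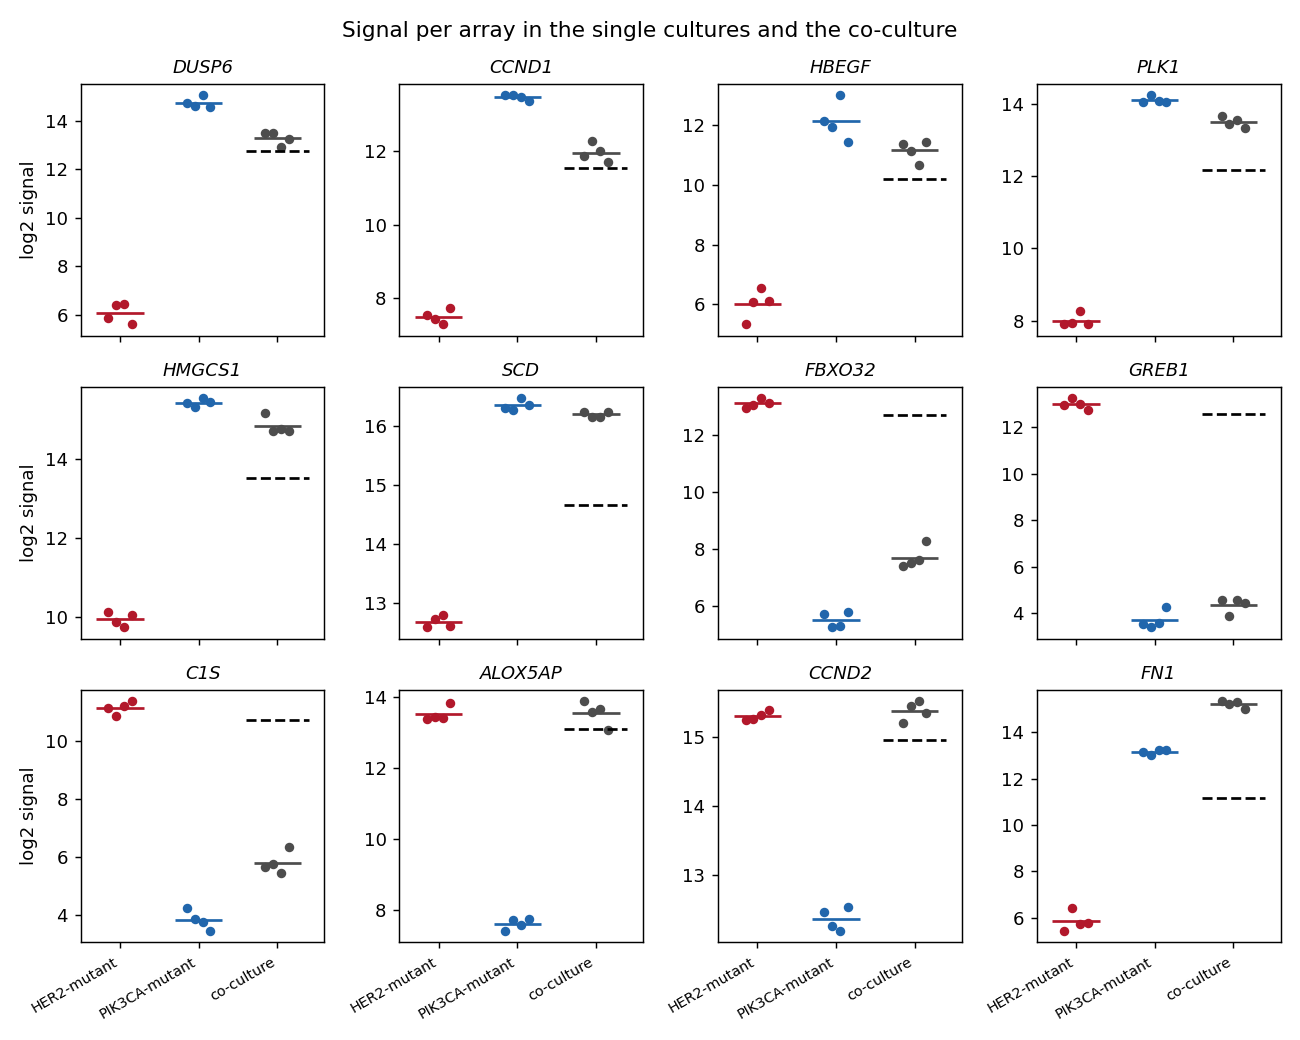
Log2 signal of 12 genes on each array, with the 3 cultures side by side; bars are group means and the dashed line is the level of a mixture of 75% HER2-mutant and 25% PIK3CA-mutant signal. ALOX5AP and CCND2 reach the HER2-mutant level in the co-culture, GREB1 stays near the PIK3CA-mutant level, and FN1 lies above both single cultures.

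Members of the signalling lists showed the contrast between the lines gene by gene. Among genes of ERK output, SPRY4 differed by -6.34, ETV5 by -6.27 and CCND1 by -5.97 on the log2 scale. In the limma fit, 17 of the 20 members were lower over all genes and 18 adjusted over the list alone, with a median of -2.74. The 3 not past the threshold over all genes were FOS (-0.47, limma adjusted p 0.0687), EGR1 (-0.02, 0.899) and MYC (0.13, 0.115). Limma's camera test, which compares a list with the other genes, gave the ERK list an adjusted p of 3.4e-11. It assumes a preset correlation between genes. Where a call was lost with the correlation estimated from the arrays, that p is given beside it as the estimated-correlation p. In the pairwise comparisons that setting changed more than the correlation. For fatty acids the estimate was -0.054, below the preset, yet the camera adjusted p rose from 1.14e-06 to 0.00262. Against the expected blend, tested with cameraPR, their adjusted p fell from 2.79e-09 to 1.14e-09. A lost call thus does not by itself show correlated genes. Of 17 FOXO targets, 13 were higher and 2 lower, over all genes and adjusted over the list alone (camera adjusted p 7.29e-05), a call lost at an estimated-correlation p of 0.109. CITED2 was higher by 3.85, BCL6 by 3.52 and IRS2 by 3.28. Among receptors and ligands of the EGFR family, the ligand genes HBEGF, TGFA and EPGN differed by -6.12, -2.01 and -1.23. The receptor gene ERBB3 was higher by 2.71, and EGFR differed by -0.57 (limma adjusted p 1.21e-06), a call lost against the tested margin of 0.5 (0.492). As a whole that list did not pass, with 1 member higher and 8 lower of 15 (camera adjusted p 0.111).

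Growth and biosynthesis genes followed the same direction as ERK output. All 30 cell cycle genes were lower in the HER2-mutant line, over all genes and adjusted over the list alone, with a median of -3.81 (camera adjusted p 3.69e-22). RRM2 differed by -6.53, PLK1 by -6.13 and CDC20 by -6.13. Of 18 cholesterol genes, 17 were lower, with a median of -2.61 (6.28e-12), among them HMGCS1 by -5.48, ACAT2 by -4.36 and FDPS by -4.28. Of 9 fatty acid genes, 8 were lower, with a median of -2.41 (1.14e-06), with SCD at -3.69 and ACSS2 at -3.10. Of 22 amino acid response genes, 18 were lower (1.73e-06, lost at an estimated-correlation p of 0.146), TRIB3 by -4.75 and SLC7A11 by -3.84. Of 14 chaperone genes of the endoplasmic reticulum, 10 were lower and 2 higher (0.00958, lost at 0.209), with MANF at -2.13 and XBP1 at -2.06. Of 23 secreted growth factor genes, 13 were lower and 3 higher (0.00117), FGFBP1 by -6.40, WNT7A by -5.29 and VEGFC by -4.01. Of 19 p53 targets, 13 were lower and 4 higher (0.00707, lost at 0.15), GDF15 by -3.23 and TP53I3 by -2.16. Glycolysis and hypoxia genes were split (0.0471, lost at 0.309), with 12 of 19 lower, as ALDOC (-2.89) and VEGFA (-2.62), and 4 higher, as ADM (2.48) and HK2 (2.00). Counts adjusted over the list alone were the same for these 7 lists.

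Antigen presentation genes went the other way, and the cytokine genes were divided. All 10 antigen presentation genes were higher in the HER2-mutant line, over all genes and adjusted over the list alone, with a median of 1.58 (camera adjusted p 2.48e-06, estimated-correlation p 0.05, at the threshold and not past it). PSMB9 was higher by 2.45, HLA-F by 2.38 and TAP1 by 2.04, and HLA genes resemble each other closely, so the source of that signal is uncertain. Of 19 inflammatory cytokine genes, 7 were higher and 5 lower, SAA1 by 5.48 against CXCL8 by -5.82 and TNFAIP2 by -3.29. VIM, a mesenchymal marker, differed by -4.49. The camera adjusted p was 0.509 for the cytokine list, 0.0516 for the mesenchymal, 0.0614 for the interferon response and 0.0614 for the matrix protease list. It was 0.728 for heat shock, 0.944 for NRF2 targets, 0.933 for luminal, 0.722 for basal and 0.452 for squamous genes. It was 0.328 for YAP targets, 0.992 for NOTCH and WNT targets, 0.971 for fibroblast markers and 0.466 for blood and endothelial markers. Median, mean and test direction did not share a sign for the heat shock, NRF2, luminal, YAP, NOTCH and WNT, and fibroblast lists.

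With the preset correlation of 0.01, 11 of the 25 lists passed. With the correlation estimated from the arrays, 5 lists passed in this comparison, with p adjusted over the lists of 0.00186 (ERK output), 0.00214 (cell cycle), 0.00186 (cholesterol), 0.00262 (fatty acids) and 0.018 (secreted growth factors). The glycolysis call (0.0471) stood close to the threshold. Over its alternatives the p ran from 0.00629 to 0.309. It was 0.0517 and 0.0504 without HER2-mutant replicate 1 or 4, 0.0617 without PIK3CA-mutant replicate 3, and 0.0514 and 0.0508 without co-culture replicate 1 or 4.

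The co-culture against the HER2-mutant single culture asked what distinguished the mixed culture from the line that made up most of its cells. The co-culture carried more signal of proliferation genes, sterol and fatty acid synthesis genes and ERK output, and less of antigen presentation genes. It carried less of many FOXO targets too, a list call lost with the correlation estimated from the arrays (p 0.121). FN1, the gene of fibronectin, showed the largest increase. GREB1, bright in the HER2-mutant line, was close to the dim level of the PIK3CA-mutant line, and FBXO32 lay between both lines. By limma, 3180 genes were higher and 3323 lower in the co-culture, and 1096 and 689 of them by at least 1 on the log2 scale. Against a tested margin of 0.5 the count was 2269. In limma, FN1 was higher by 9.37 ± 0.14 (SE, adjusted p 1.43e-22), reaching 15.22 ± 0.14 against 5.85 ± 0.42 (SD, n = 4 each). CLDN1 was higher by 8.24, THBS1 by 8.16, ABCC3 by 7.62, DUSP6 by 7.20 and NT5E by 6.88. GREB1 differed by -8.63, TSHZ2 by -6.42, WNT4 by -5.57, FBXO32 by -5.40, C1S by -5.32 and CD36 by -5.18.

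All 30 cell cycle genes were higher in the co-culture than in the HER2-mutant line, over all genes and adjusted over the list alone, with a median of 3.40 (camera adjusted p 8.43e-28). PLK1 was higher by 5.51, CCNB2 by 5.40 and CDC20 by 5.38. Also higher were 17 of 18 cholesterol genes (4.02e-16; HMGCS1 by 4.89, ACAT2 by 4.49), 9 of 9 fatty acid genes (1.7e-08; SCD by 3.53) and 16 of 20 ERK output genes (1 lower; 7.05e-11). Within the ERK list ETV5 was higher by 5.96 and EPHA2 by 4.84. Higher were also 19 of 22 amino acid response genes (2 lower; 4.21e-09, lost at an estimated-correlation p of 0.0753), with TRIB3 by 4.68 and SLC7A11 by 4.25, and 12 of 23 secreted growth factor genes (1 lower; 0.000392), with FGFBP1 by 5.00 and WNT7A by 3.33. The EGFR ligand HBEGF was higher by 5.15. Chaperones (10 of 14 higher and 2 lower, 0.000288), p53 targets (11 of 19 higher and 2 lower, 0.00607) and mesenchymal genes (9 of 17 higher and 3 lower, 0.035, VIM by 4.34) passed with the preset correlation only, with estimated-correlation p of 0.121, 0.125 and 0.125. Lower were 9 of 10 antigen presentation genes (10 adjusted over the list alone; 3.54e-07), with PSMB9 at -2.32 and HLA-F at -1.85. Also lower were 11 of 17 FOXO targets (2 higher; 0.000242, ERBB3 by -2.09) and 9 of 21 interferon response genes (2 higher; 0.0229, SAMD9L by -2.89), both lost at estimated-correlation p of 0.121 and 0.125. Apart from antigen presentation, the counts of these 12 lists adjusted over the list alone were those over all genes. EGFR did not pass the threshold (-0.03, limma adjusted p 0.744), and the sign turned without HER2-mutant replicate 3 (0.023, adjusted p 0.84).

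Of the 12 lists past the threshold in this comparison, 6 passed with the correlation estimated from the arrays, those of the cell cycle (p 0.00106), cholesterol (0.000829), fatty acids (0.00106), ERK output (0.00106), antigen presentation (0.0347) and secreted growth factors (0.0119). The mesenchymal call was lost without PIK3CA-mutant replicate 1 (0.0759) or 4 (0.0692) and without co-culture replicate 1 (0.0802), in a range from 0.0188 to 0.125 over its alternatives.

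**Figure D2:**
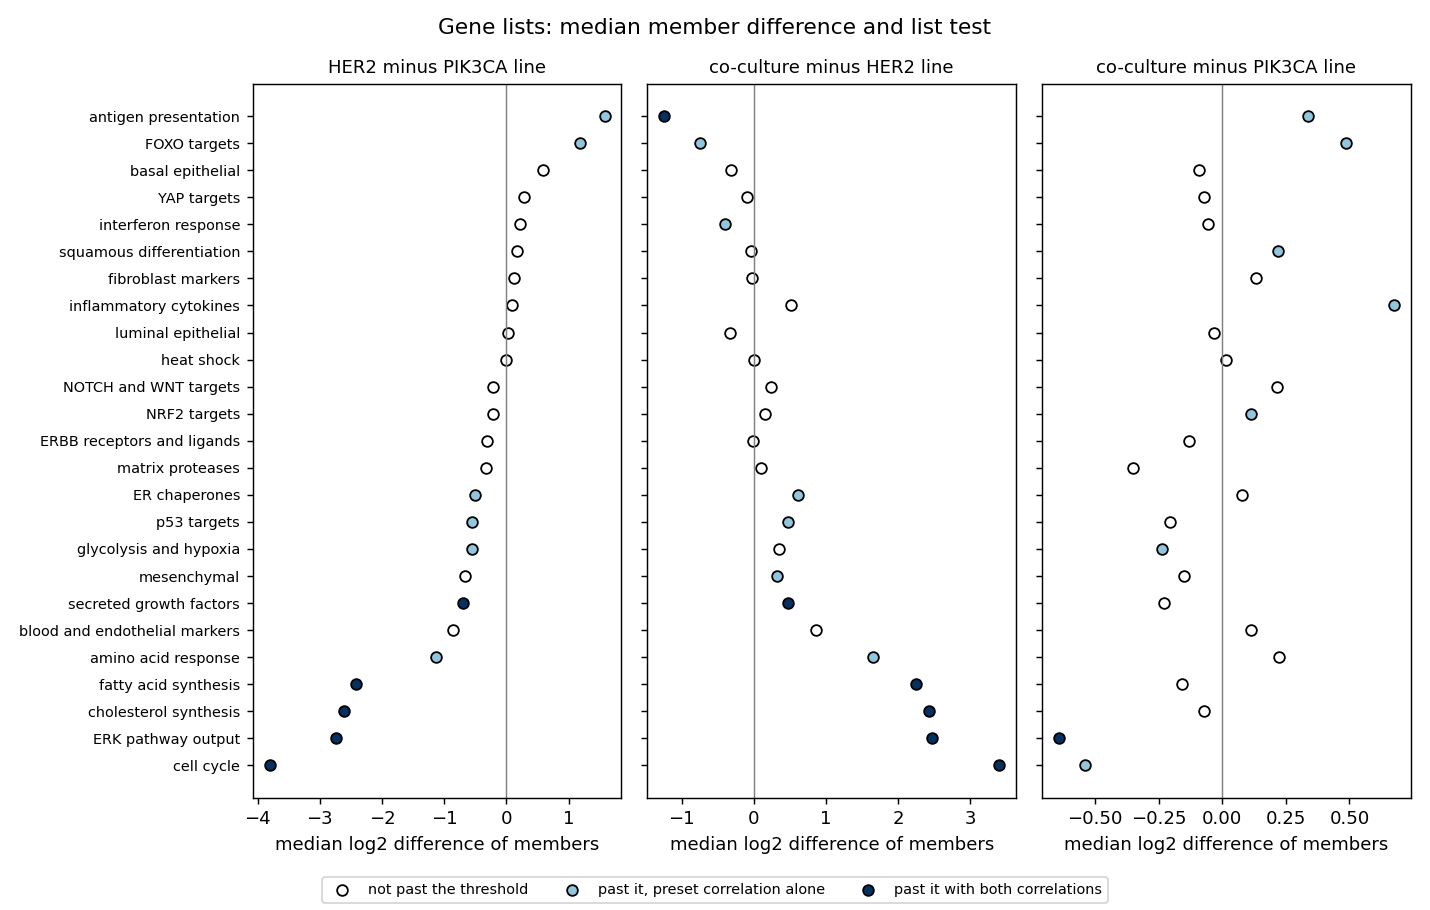
Median log2 difference of the tested members of 25 gene lists in each of the 3 pairwise comparisons, with one horizontal scale per panel; open circles did not pass, light blue circles passed with the preset correlation alone, and dark circles passed with the estimated correlation too. The cell cycle list has the largest median in both comparisons with the HER2-mutant line, -3.81 and 3.40.

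The co-culture against the PIK3CA-mutant single culture asked what the HER2-mutant cells added to, or the joint growth changed from, that line. Fewer genes differed. ERK output was lower in the co-culture, the 1 list whose call held with the correlation estimated from the arrays. Part of the cell cycle and glycolysis genes were lower, and part of the FOXO targets, inflammatory cytokines, NRF2 targets and squamous genes were higher. Transcripts bright in the HER2-mutant line, such as ALOX5AP and CCND2, were higher too. By limma, 1413 genes were higher and 1860 lower, and 189 and 249 of them by at least 1 on the log2 scale. Against a tested margin of 0.5 the count was 439. In limma, ALOX5AP was higher by 5.95 ± 0.14 (SE, adjusted p 1.24e-18), at 13.56 ± 0.34 in the co-culture and 7.61 ± 0.15 in the PIK3CA-mutant line (SD, n = 4 each). SERPINA1 was higher by 5.58, EEF1A2 by 3.47, FAXDC2 by 3.13, CCND2 by 3.00 and SELENOP by 2.90. ANGPTL4 differed by -3.78, OSBP2 by -3.47, TGM2 by -3.37, INSC by -2.55, MALL by -2.49 and IGFBP2 by -2.47.

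Of the 20 ERK output genes, 12 were lower and 1 higher in the co-culture than in the PIK3CA-mutant line over all genes, and 15 were lower adjusted over the list alone, with a median of -0.64 (camera adjusted p 5.13e-07). SPRY4 differed by -2.25, PHLDA1 by -2.04, CCND1 by -1.51 and DUSP6 by -1.45. The EGFR ligands EPGN, TGFA and HBEGF differed by -1.70, -1.37 and -0.97, EGFR by -0.61 (limma adjusted p 4.01e-06) and ERBB3 by 0.62 (0.00182). FOXO targets were higher in 9 of 17 (10 adjusted over the list alone) and lower in 1 (3.98e-05, lost at an estimated-correlation p of 0.191), FBXO32 by 2.18, BCL6 by 1.95 and CITED2 by 1.77. Inflammatory cytokine genes were higher in 10 of 19 and lower in 2 (2.05e-05, lost at 0.26), with IL1B at 1.93, SAA1 at 1.80, TNFAIP3 at 1.54 and CXCL1 at 1.51. Of 30 cell cycle genes, 17 were lower and 2 higher (3.98e-05, lost at 0.191), RRM2 by -1.47 and BIRC5 by -0.95. Glycolysis genes were lower in 8 of 19 (0.00842, lost at 0.26), with PGAM1 by -0.67 and P4HA1 by -0.61. Antigen presentation genes were higher in 6 of 10 (0.0145, lost at 0.264), HLA-F by 0.52 and TAP1 by 0.51. Squamous genes were higher in 6 of 18 and lower in 1 (0.0194, lost at 0.348), S100A8 by 2.42, KRT10 by 2.39, S100A7 by 2.30 and S100A9 by 2.09. NRF2 targets were higher in 4 of 17 (5 adjusted over the list alone) and lower in 1 (2 adjusted over the list alone; 0.0194, lost at 0.264), AKR1C1 by 2.53 and FTL by 2.36. S100A and AKR1C genes have close relatives, so the source of their signal is uncertain.

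With the correlation estimated from the arrays, only the ERK output list of these 8 passed (p 0.0171). The NRF2 call was also lost without co-culture replicate 1 (0.0586), in a range from 0.00683 to 0.264. HBEGF was lost with a robust estimate of the spread (adjusted p 0.0647, in a range from 0.00128 to 0.607). Against the tested margin of 0.5, HBEGF, BIRC5, PGAM1, P4HA1, HLA-F, TAP1, EGFR and ERBB3 did not pass.

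The share of signal asked whether the co-culture RNA looked like a blend in the proportion of its cells. On the linear scale of the signal it did not match 75%, and the shares of both directions differed. With the signal raised to the power 0.25 the shares came closer, at 25.8% and 31.3%, a gap of 5.5 points against 24.5 at power 1. Powers below 1 undo a signal that rises faster than the RNA amount, the opposite of compression. The size of the gap thus depends on the response of the array, which was not measured. Among genes higher in the HER2-mutant line, the co-culture carried a median of 18.4% of the difference between the lines (SD 2.94 over the 4 co-culture arrays, which ran from 14.3% to 21.4%). Among genes higher in the PIK3CA-mutant line the share of the HER2-mutant line was 42.9% (SD 2.79, from 38.9% to 45.3%). The mean of both was 30.7%. With genes chosen and measured on all arrays rather than in separate sets of replicates, the medians were 18.2% and 42.9%. Of these genes, only 30 of 1150 of the first kind and 117 of 1563 of the second reached a share of 75% or more. With the names of the single cultures exchanged, the shares would read 81.6% and 57.1%, and no signal used here tells which line is which.

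**Figure D3:**
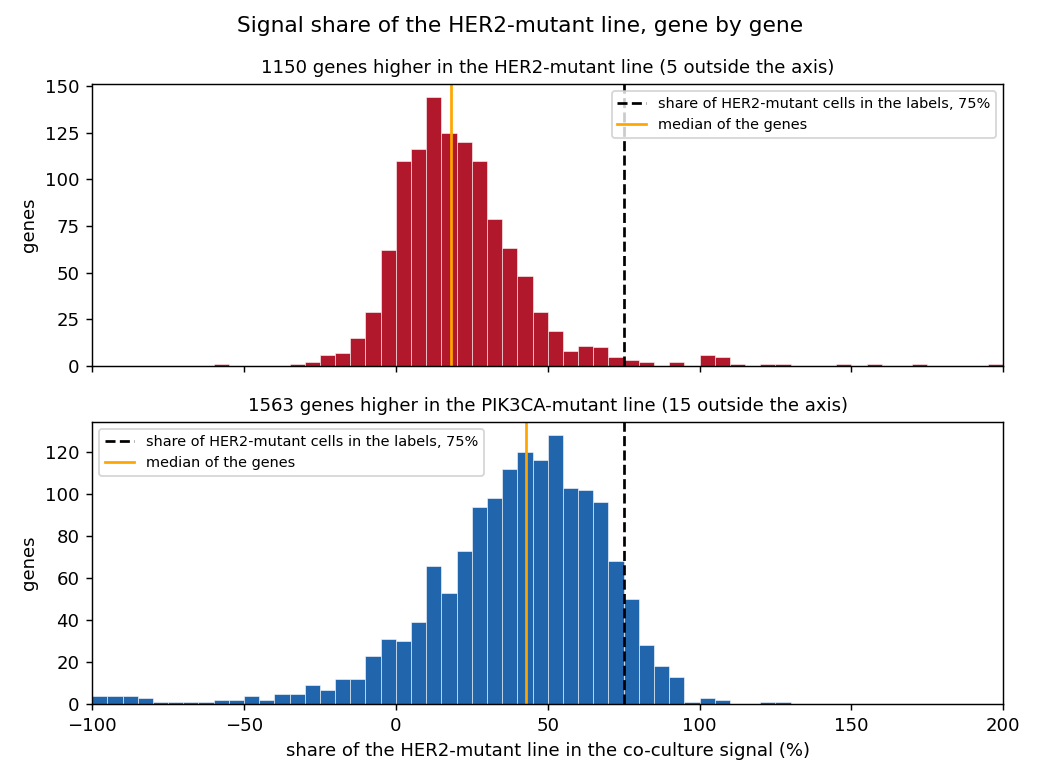
Histograms of the share of the HER2-mutant line in the co-culture signal, in percent per gene in bins of 5%, for the 1150 genes higher in the HER2-mutant line and the 1563 higher in the PIK3CA-mutant line; the dashed line is 75% and the solid line is the median. Of these genes, 5 and 15 lie outside the plotted axis.

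The co-culture against the mixture asked which genes departed from a blend of 75% HER2-mutant and 25% PIK3CA-mutant signal, formed on the linear scale. Growth, sterol and fatty acid synthesis and amino acid response genes lay above the blend, and antigen presentation genes and transcripts such as GREB1 and FBXO32 lay below it. By the limma standard errors, 2357 genes were above and 2850 below, 40.8% of those tested, and 1252 and 1607 of them by at least 0.5 on the log2 scale. With the share estimated from the signal, 30.7%, 720 genes were above and 1679 below, 2399 in all, and 310 and 819 of them by at least 0.5. At 25% there were 717 above and 1595 below, 2312 in all, and 312 and 808 of them by at least 0.5. Both the count and the balance of directions thus depended on the share taken for the blend. The 30.7% is the mean of 18.4% and 42.9%, taken from the same co-culture arrays. At a share between these, typical genes higher in either line lie below the blend by construction. The excess of genes below at 30.7% and at 25% therefore does not by itself show a change in the co-culture.

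FN1 lay 4.04 ± 0.14 above the mixture on the log2 scale (SE, limma adjusted p 1.18e-15), SERPINA1 3.15, S100A7 3.00, CLDN1 2.87, PHGDH 2.70, ALDH3B2 2.67, CHRNA9 2.40 and DUSP5 2.40. The histone genes H3C2 and H2AC11, whose near-identical copies make the source of the signal uncertain, lay 2.65 and 2.45 above. GREB1 stood at -8.22 ± 0.20 from the mixture (SE, limma adjusted p 2.34e-18), TSHZ2 at -6.01, WNT4 at -5.16, FBXO32 at -4.99, C1S at -4.91, CD36 at -4.77, CHI3L2 at -4.74, EDN1 at -4.72, CYP3A5 at -4.45 and C1R at -4.40. ERBB3 stood at -1.75. EGFR stood at -0.20 (limma adjusted p 0.0241), a call lost without HER2-mutant replicate 3 (0.0651) and without co-culture replicate 2 (0.0697) or 4 (0.0741), in a range from 3.7e-05 to 0.13.

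All 30 cell cycle genes lay above the mixture, over all genes and adjusted over the list alone, with a median of 1.16 (limma cameraPR adjusted p 3.4e-21), TOP2A by 1.93 and CCNB2 by 1.64. So did 17 of 18 cholesterol genes (2.36e-17; ACAT2 by 1.93, DHCR7 by 1.73), 8 of 9 fatty acid genes (2.79e-09; SCD by 1.54) and 18 of 22 amino acid response genes, with 3 below (1.03e-10; STC2 by 2.26). Chaperones lay above in 10 of 14 and below in 2 (1.89e-05; XBP1 by 1.47, HERPUD1 by 1.41), ERK output above in 11 of 20 and below in 1 (0.000452; ETV5 by 1.64) and secreted growth factors above in 7 of 23 and below in 1 (0.0148; INHBA by 2.06). The p53 targets lay above in 9 of 19 and below in 2 (0.0128, lost at an estimated-correlation p of 0.0925) and the mesenchymal genes above in 9 of 17 and below in 3 (0.0484, lost at 0.0782), VIM by 1.67. Antigen presentation genes lay below in 9 of 10 (3.33e-08; PSMB9 by -1.99, HLA-F by -1.53), FOXO targets below in 11 of 17 and above in 2 (0.000204) and interferon response genes below in 9 of 21 and above in 2 (0.0196, lost at 0.0624), SAMD9L by -2.55. These counts adjusted over the list alone were the same.

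The distances of single genes and the counts of list members depended on the share too. At 30.7%, FN1 lay 2.59 above the blend, CLDN1 1.42, TOP2A 0.56, ACAT2 0.62, SCD 0.32, ETV5 0.21 and CCNB2 0.23, and GREB1 stood at -6.93, ERBB3 at -0.81 and HLA-F at -0.67. SERPINA1 lay further above, by 4.09. All named genes kept their direction at 30.7% and at 25%. Past the threshold above the blend at 30.7% were 5 of 30 cell cycle, 8 of 18 cholesterol, 5 of 9 fatty acid, 13 of 22 amino acid response, 5 of 14 chaperone, 3 of 23 secreted growth factor, 2 of 17 mesenchymal, 1 of 20 ERK output and 1 of 19 p53 genes. Below it were 9 of 10 antigen presentation, 6 of 17 FOXO and 6 of 21 interferon response genes.

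Which lists passed depended on the share. At 30.7%, 13 lists passed with the preset correlation, against 12 at 75%. The cholesterol, fatty acid, amino acid, chaperone and antigen presentation lists passed in the same direction at both. Of the lists that passed at 30.7% and not at 75%, cytokines (adjusted p 0.00256), NRF2 targets (0.0347) and squamous genes (0.0368) were above the blend, and basal genes (0.00397), glycolysis (0.0322), ERBB receptors and ligands (0.0486) and luminal genes (0.0486) below it. The cell cycle list did not pass at 30.7% (0.129, and 0.831 at 25%), and its adjusted p ran from 4.02e-28 to 0.831 over its alternatives. The ERK output list turned to below the mixture (0.0168, and 0.00161 at 25%), and the secreted growth factors turned too without passing (0.799 and 0.548). Shares below 42.9%, that of genes higher in the PIK3CA-mutant line, favour such a turn by construction. FOXO, interferon, mesenchymal and p53 genes no longer passed at 30.7% (0.142, 0.0656, 0.358 and 0.654), nor did ETV5 and CCNB2, and VIM lost its call at 25% (0.24, adjusted p 0.154). The mesenchymal call was also lost with the replicate number as a block (0.0654), with no filter on dim probe sets (0.0541), without PIK3CA-mutant replicate 1 (0.101), 2 (0.0513) or 4 (0.11) and without co-culture replicate 1 (0.127), 3 (0.0608) or 4 (0.0538), in a range from 0.0245 to 0.513.

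Genes outside both single cultures needed no assumed share, since no blend of the 2 lines can lie above both or below both. In the co-culture, fibronectin, the interleukin gene IL1B, the antiprotease SERPINA1, squamous S100A genes and the serine synthesis gene PHGDH rose above both lines. The sulfotransferase gene SULT1E1, the receptor gene ROR1 and the calcium pump gene ATP2B4 fell below both. In an intersection of both limma contrasts, 128 genes lay above both lines and 108 below both, 1.85% of the genes tested, and 28 and 9 of them by at least 1 on the log2 scale. Without co-culture replicate 3 the count was 151. It was 146 without a trend of the spread with signal, and 525 when each contrast was adjusted on its own.

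By the smaller of both differences, SERPINA1 rose by 2.80 on the log2 scale (limma adjusted p 9.66e-10), at 10.43 ± 0.08 in the co-culture, 7.63 ± 0.39 in the HER2-mutant line and 4.85 ± 0.27 in the PIK3CA-mutant line (SD, n = 4 each). CHRNA9 rose by 2.31, S100A7 by 2.30, FN1 by 2.07, IL1B by 1.93, H2BC14 by 1.51, NUAK2 by 1.45, ALDH3B2 by 1.42, EGR3 by 1.39 and PHGDH by 1.36. H2BC14 has near-identical copies, and its level in the single cultures, 3.14 and 4.39, was close to background. The EGR3 call (0.0169) was lost without co-culture replicate 2 (0.0603), 3 (0.0535) or 4 (0.0667), in a range from 0.000726 to 0.305. SULT1E1 stood at -2.10, ROR1 at -1.47, MIOS at -1.40, CAVIN2 at -1.32, EPB41L4A at -1.29, ATP2B4 at -1.28, RGS2 at -1.15, TMEM40 at -1.01, MAP2 at -0.97 and TLL1 at -0.95.

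Of 374 list members tested, 14 lay above both lines and 7 below both, 5.6% against 1.85% of all genes. Besides those given with the largest differences, above both were the squamous genes PI3 (1.15) and S100A9 (1.07), the YAP target CCN2 (1.10), the chaperone pathway gene HERPUD1 (1.09) and STC2 (0.88) of the amino acid response. Also above both were ATF4 (0.44) and the cholesterol genes MVK (0.56) and DHCR7 (0.29). The S100A9 call was lost with a robust estimate of the spread (adjusted p 0.0627, in a range from 5.9e-05 to 0.0627). Below both were the protease inhibitor TIMP3 (-0.88), the FOXO target CCNG2 (-0.75) and the interferon response gene SAMD9 (-0.65), and also EPGN (-0.47), NDRG1 (-0.40) of the glycolysis list and the basal keratin gene KRT5 (-0.20). From the ERK list DUSP5 lay above both (0.92, adjusted p 0.0145) and FOS below both (-0.97, 0.0167). The DUSP5 call was lost without PIK3CA-mutant replicate 1 (0.0791) or 2 (0.0699) and without co-culture replicate 1 (0.0751) or 2 (0.0712), in a range from 0.00158 to 0.105. The FOS call was lost without HER2-mutant replicate 2 (0.0704) or 3 (0.0855) and without co-culture replicate 3 (0.0927) or 4 (0.0502), in a range from 1.47e-06 to 0.303.

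The calls of smaller size among these depended on single arrays or settings. ATF4 was lost without a trend of the spread (adjusted p 0.114, in a range from 0.00119) and MVK without co-culture replicate 2 (0.0521, in a range from 0.001). DHCR7 was lost without PIK3CA-mutant replicate 1 (0.0952), 2 (0.0698) or 3 (0.116) and without co-culture replicate 2 (0.151) or 3 (0.124). It was also lost with quantile normalization (0.121), median centring (0.0755) and no trend of the spread, in a range from 0.00332 to 0.286. EPGN was lost without HER2-mutant replicate 1 (0.108), 3 (0.0746) or 4 (0.143), without any PIK3CA-mutant replicate (0.0618 to 0.0713) and without co-culture replicate 1 (0.162), 2 (0.113) or 3 (0.22). It was also lost with no filter on dim probe sets (0.0622) and no trend (0.143), in a range from 0.00234 to 0.22. KRT5 was lost without HER2-mutant replicate 2 (0.0703), 3 (0.121) or 4 (0.0697), without PIK3CA-mutant replicate 2 (0.0505), 3 (0.0549) or 4 (0.0551) and without co-culture replicate 2 (0.0712), 3 (0.126) or 4 (0.0864), and with no trend (0.663), in a range from 0.00165. NDRG1 kept its call, with adjusted p up to 0.0492.

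**Figure D4:**
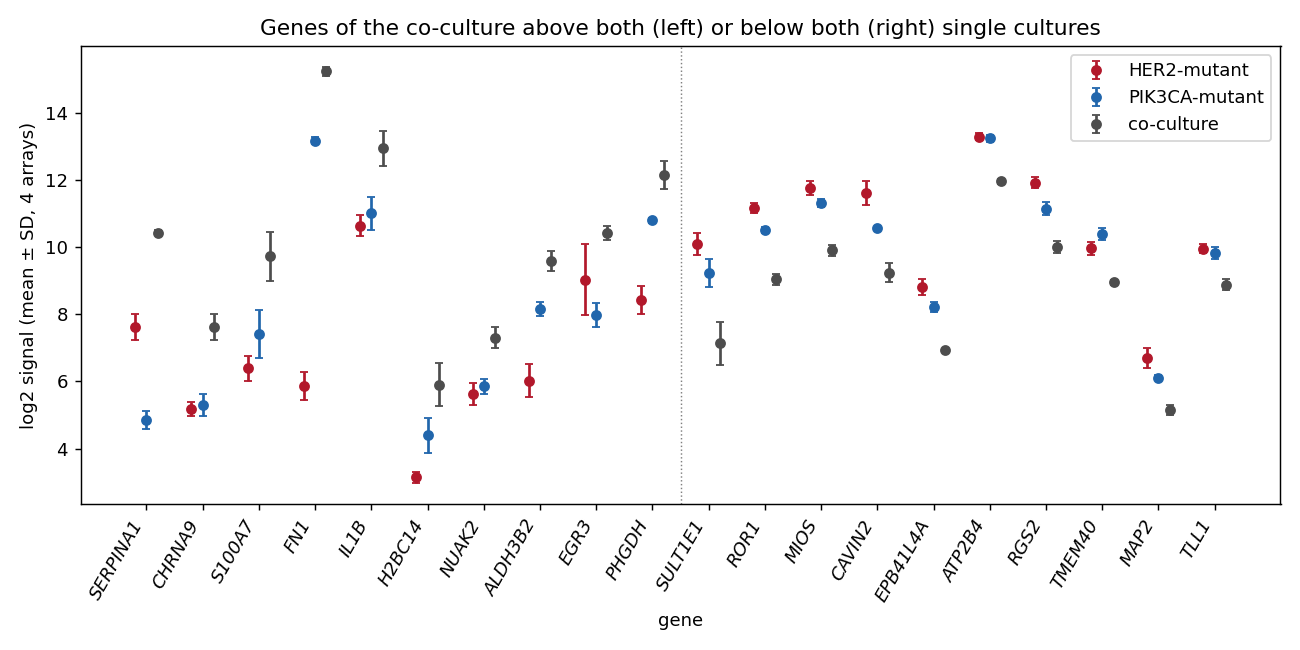
Mean log2 signal and SD (n = 4 arrays) in the 3 cultures for the 10 genes furthest above and the 10 furthest below both single cultures. The co-culture mean lies outside both lines in each gene, with the smaller difference from 1.36 (PHGDH) to 2.80 (SERPINA1) above and from -0.95 (TLL1) to -2.10 (SULT1E1) below.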

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

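A value is listed here when one of the 4 arrays of a group stood apart from the other arrays, with a gap, as a part of the range of its group, above the critical value of Dixon's ratio. Of 441 groups of values tested, 21 held such an array. Chance alone gives about 1 in 20, or 22.05, so their number is that of chance. At most 4 fell on one array (PIK3CA-mutant replicates 2 and 3), and no explanation was weighed. All values are log2 signals.

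In the HER2-mutant line, ALOX5AP was at 13.85 on replicate 4 against 13.40 to 13.45 on the others, and BCL6 at 14.44 on replicate 1 against 14.09 to 14.12. PLK1 was at 8.26 on replicate 3 against 7.90 to 7.93, and FTL at 14.18 on the same array against 13.94 to 13.97. ANGPTL4 was at 3.62 on replicate 4 against 4.44 to 4.46, near background, and P4HA1 at 10.44 on that array against 9.97 to 10.04. The median of the mesenchymal list was 6.44 on replicate 2 against 6.79 to 6.85, and that of the YAP targets 9.64 on the same array against 9.85 to 9.89.

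In the PIK3CA-mutant line, replicate 2 stood apart for WNT4 (5.44 against 5.69 to 5.73), PLK1 (14.26 against 14.07 to 14.10), XBP1 (10.98 against 11.21 to 11.25) and WNT7A (8.97 against 9.29 to 9.33). Replicate 3 stood apart for CASP14 (12.95 against 12.16 to 12.25), SPRY4 (11.22 against 10.24 to 10.30), VEGFA (13.64 against 13.22 to 13.28) and SULT1E1 (8.59 against 9.42 to 9.46). Replicate 1 did for LIPG (11.33 against 11.75 to 11.81) and CCNG2 (11.60 against 11.47 to 11.49).

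In the co-culture, HMGCS1 was at 15.18 on replicate 1 against 14.71 to 14.77, and INSC at 5.42 on the same array against 4.31 to 4.43. H3C2 was at 8.01 on replicate 4 against 8.36 to 8.40.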

How the results depend on the processing

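The blend at 25%, and the lists against blends at other shares than 75%, were chosen after the data were seen. Of 4739 values of named genes under alternatives, 4668 kept direction and call, 70 kept direction and lost the call, and 1 turned. Of 970 list tests, 913 kept both, 53 lost the call and 4 turned. Of 927 counts of list members, 19 moved by over 1.5 times, all against the blend at 30.7% or 25%, as for the cell cycle list (30 at 75%, 5 at both). Leaving out each array gave 7161 to 7583 genes between the single cultures, 6042 to 6435 for the co-culture against the HER2-mutant line, 2772 to 3502 against the PIK3CA-mutant line and 4607 to 5182 against the blend. Outside both, the count ran from 151, without co-culture replicate 3, to 232.

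Counts of genes and lists that moved by over 1.5 times did so under these settings. With a tested margin of 0.5 they were 3524, 2269 and 439 for the 3 pairwise contrasts, by construction. Against the blend the count was 2399 at the estimated share (1129 by at least 0.5) and 2312 at 25% (1120 by at least 0.5), a share closer to the co-culture signal. Outside both it was 146 without a trend of the spread and 525 with each contrast adjusted on its own. With estimated correlations, 5, 6 and 1 lists passed in the pairwise comparisons, a setting that raised p also where the estimate was below the preset. With replicate number as a block the totals were 7604, 6506, 3335, 5258 and 243.

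Against the blend, the ERK list turned to below it at the estimated share (adjusted p 0.0168) and at 25% (0.00161), and the secreted growth factors turned without passing (0.799 and 0.548). A lower share of the HER2-mutant line raises the blend for genes higher in the other line. EGFR in the co-culture against the HER2-mutant line, never past the threshold, ran from -0.086 to 0.023 with single arrays left out. The share was 13.3% over genes that differed by at least 2 and were higher in the HER2-mutant line, and the cause was not tested. Slopes on the log2 scale gave 29.8%, 23.2% and a mean of 26.5%, since a blend is not additive there. Quantile normalization turned the genes outside both from 54.2% above to 49.4%. Where the dimmer group lies near the negative controls (3.39 to 3.79), as for GREB1 (3.69) and C1S (3.84), the difference is a lower limit in size.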

Other observations

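The tests of one share for every gene, of exchanged labels, of changed expression and of dim probe sets were chosen after the results were seen, and so were the gene groups in the last 2 paragraphs.

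Other splits of the arrays tested whether arrays can be exchanged between groups, and argued against that for the pairwise counts. With 35 splits, 1 in 35 is the smallest proportion such a test can give. For each pairwise comparison 1 of 35 splits, the real one, gave as many genes, 7587, 6503 and 3273, and the highest of the others gave 0. The other pairwise splits mix arrays of different groups too, so their 0 does not measure the calls that noise alone would give. Against the blend 1 of 100 drawn splits, the real one, gave as many genes, 5207, and the highest other 3347. Outside both it was 1 of 100, with 236 genes, and the highest other 37. For these 2 counts the other splits mix arrays of lines that differ, which widens the spread within groups, so they do not test a co-culture against 2 distinct lines.

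The signal of the co-culture lay further from the HER2-mutant line than its 75% of cells. Compression confined to bright signals was argued against as the source of the 24.5 points between the shares of both directions. Genes dimmer than the median still had a gap of 24.3. That split does not test a response that acts alike at all levels. Normalization stays open. Quantile normalization left 24.9, but the deposited values already had near equal medians, so it could change little. It does not undo the unnamed method behind those values. One share for every gene was argued against as the whole account, whatever response the genes share. Of 2625 genes with a match within 0.25 in both single cultures, 289 (11.01%) differed from it by over 1 in the co-culture. That percent lay just past a bound set after the results were seen, and both genes of a matched pair could count. A simulated blend gave 0 of 2617, a count all but fixed by the matching, since its noise was the residual spread alone. A lower share of HER2-mutant RNA beside other changes, or with a response that differs by gene, stays open, and exchanged names of the single cultures (mean share 69.3%) cannot be told apart from the given ones without a genotype signal. Changed expression in the co-culture is a candidate explanation for the 236 genes outside both lines. Of the 2713 genes that passed the rule for the share when chosen on all arrays, 40 (1.47%) are among them. These 2713 genes differ by at least 1 between the lines, so a changed level counts here only if it passes beyond both. The 1.47% therefore does not measure how many of them changed. The shares given rest on genes chosen by the same rule within each set of replicates. Whether changed expression lowers the share stays open, and bulk arrays do not assign it to one line.

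Of the 236 genes outside both lines, 8.05% (19 genes) belong to near-identical families, so shared probes of these families cannot account for most of them. Within such families shared probes stay open. Of 53 histone genes, 16 lay above both lines, against 1.85% of all genes outside both. Dim probe sets stay open, since 26.3% (62 genes) were below the median signal in the single culture nearest to the co-culture, and the stricter filter, which 4 co-culture arrays alone can pass, does not test them. By the bounds set, a single co-culture array was not decided, since leaving out replicate 3 kept 63.1% of the calls (149 genes). Leaving out the others kept 173, 159 and 178. At least 149 calls thus stayed in each of these fits. In each, 233 genes kept their side, a count all but fixed because the genes were chosen with the same arrays. The calls that stayed argue against a single array as the source of the 236 genes as a set, and leave it open for the calls that were lost. A difference in handling cannot be told apart from the co-culture, since 0 labels name a batch, date, scan or chip. A biological change in the co-culture therefore remains a hypothesis beside these.

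Among 53 histone genes, whose near-identical copies make single names uncertain, 39 were higher and 1 lower in the co-culture than in the HER2-mutant line, with a median of 1.00 on the log2 scale. Against the PIK3CA-mutant line 30 were higher and 5 lower, and 16 lay above both lines and 0 below. With quantile normalization 15 lay above both, with median centring 16. Among 15 complement genes, 8 were higher and 2 lower in the HER2-mutant than in the PIK3CA-mutant line, and 8 were lower in the co-culture than in the HER2-mutant line and 0 higher, also with both scalings. Of all genes tested, 59.5% differed between the lines and 51.0% between the co-culture and the HER2-mutant line. The number of complement genes that differed thus does not by itself set the group apart. C3 was at 16.13 in the HER2-mutant line, 10.84 in the PIK3CA-mutant line and 13.13 in the co-culture, and CFB at 11.37, 6.15 and 7.44.

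Of 26 immediate-early genes, 4 lay above both lines and 3 below. EGR3 (1.39), NR4A1 (1.19), EGR4 (1.09) and IER5 (0.82) were above. RGS2 (-1.15), FOS (-0.97) and DUSP1 (-0.77) were below. The fit took a common spread for the 3 groups, while some of these genes varied most in the HER2-mutant line. For EGR3 the SD was 1.06 there, 0.36 in the PIK3CA-mutant line and 0.21 in the co-culture, and for FOS 0.72, 0.24 and 0.24. For EGR4 and RGS2 the HER2-mutant line did not have the largest SD. The EGR3 and FOS calls were lost with several arrays left out in turn, as given with their values in the report. In those fits the differences stayed at 1.31 to 1.40 and at -0.96 to -0.81. Both calls were also lost without a trend of the spread (limma adjusted p 0.116 and 0.13) and with a robust trend (0.305 and 0.303). Against the general trend of bright HER2-mutant transcripts, ALOX5AP, CCND2 and EEF1A2 did not differ from the HER2-mutant line past the threshold (0.03, 0.07 and -0.26, limma adjusted p 0.862, 0.495 and 0.123). CCND2 was at 15.37 in the co-culture, 15.30 in the HER2-mutant and 12.37 in the PIK3CA-mutant line. FAXDC2 was at 8.96, 9.50 and 5.84, lower by -0.53 than in the HER2-mutant line (0.00861).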
